A study of Caenorhabditis elegans with 2 samples.

How the data were processed

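Chromatin immunoprecipitation with sequencing (ChIP-seq) reads out where a tagged protein is on the genome. The series holds 2 biological replicates of a single group, mid-stage embryos of worms with a tag at the endogenous ztf-29 gene, each with technical replicate number 1 per the labels. The labels name a possible control experiment, which was not analysed here. The peak lists have a parent file besides the alignments, whose type the deposited readme does not state. The aligner, the peak caller and their versions are not given in the sources used here, nor are the read length and the read depth, so that no value here could be set against depth.

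Each replicate has a list of ranked candidate peaks and a thresholded list made from its own alignments, and the series has 2 more such pairs, made from the alignments of both replicates together, per the deposited readme. The deposited signal in each peak's line is the peak caller's value, never negative and on a scale the sources do not state, and it was used only to rank or describe peaks within a list. The deposited score is the IDR on a scale of at most 1000, and the ranked lists also give the score of minus log10 of the global IDR, at most 5, per the deposited values. The global IDR, called the IDR below, is an expected share among all peaks ranked at least as high as a given peak. It is the share that does not recur between a pair of samples or pseudo-samples. Every listed peak had an IDR of at most 0.01 in the matching ranked list. Some candidates reached that limit and were absent from the lists (126 for the conservative list). The readme gives the thresholded lists an extra parent file of unstated type. Within the conservative list 28 peaks were redundant through overlap with a neighbour.

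The peaks were placed on the reference genome WBcel235, which is ce11, with the gene annotation of Ensembl release 115. The products of tRNA genes were taken from the RefSeq annotation of the same assembly. Annotated worm 5' ends are often trans-splice sites, so that distances to a start are to the annotated end and not to a measured initiation site. Overlap meant at least 1 bp. A promoter window ran from 500 bp upstream to 100 bp downstream of any annotated protein-coding start. Failed candidates were ranked peaks with an IDR over the limit and no overlap with a listed peak (53944 for the conservative list). A summit belonged to the first class that applied, in the order promoter window, 5' UTR, coding exon, 3' UTR, intron, non-coding RNA gene and intergenic.

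Shares have exact (Clopper-Pearson) intervals at 95%, which cover counting error only. Peaks were compared with failed candidates by Fisher's exact test, two-sided. RNA genes within 200 bp of a summit and the overlap of the replicates were compared with 1000 circular shifts of the peaks within their chromosomes, and the two-sided p is 2 times the smaller tail. Gene lists were 37 sets named by family or pathway, tested where at least 5 members had a candidate in the promoter window, over a background of genes with such a candidate. Words of 6 bases on either strand within 50 bp of the summit were compared with a window of the same size starting 250 bp away, on 1 side drawn at random for each peak (the plan said either side), by the exact McNemar test. P-values were adjusted by the method of Benjamini and Hochberg within each family, over classes, lists or words, and 0.05 was the threshold. The gene lists, tests, main alternatives and the rule for named genes were fixed before the data were examined. The rule took ztf-29, the genes with a start within 1000 bp of the 25 strongest conservative peaks listed in both replicates, up to 3 members with the highest signal of each list with a member at a peak, and the 5 words with the smallest p. Other features named in the text were chosen after their values were seen. With 2 samples of a single group, p-values compare peaks or genes within these lists, not conditions.

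Alternatives were other overlap rules, the full list, the better-ranked part of each list by signal, each replicate's own list, other promoter windows and distances, other backgrounds, words of 8 bases and other control windows. The methods were tested on simulated data. A gene list planted among 7311 genes was recovered in 100 of 100 runs, with 3 false calls in 3100 other tests. A planted word was recovered in 10 of 10 runs, with 2 false calls in 20790 tests. A planted RNA class was recovered in 20 of 20 runs, with 1 false call in 140 tests. The planted word was taken out of every flank, so its recovery was fixed by construction. Summit and flank windows were swapped at random there, so those false calls do not cover a difference in base composition between summits and flanks. Smaller effects were not simulated. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.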

Results

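The study mapped where the protein of ztf-29, a gene of the zinc finger family, sits on the genome of Caenorhabditis elegans embryos. Worms of strain RW12283 carried a TY1, EGFP and 3xFLAG tag, inserted by CRISPR at the endogenous gene. Mid-stage embryos from bleached adults, with an age of 0 hour in the labels, were used whole. Sonicated chromatin with a size range of 200 to 800 bp was immunoprecipitated with an antibody against GFP. The samples form a single group of 2 biological replicates, so no treatment or genotype was compared. The data are peak lists on the ce11 assembly, and the read depth of each library is unknown. Replicate 1 had 466 listed peaks among 38705 candidates, and replicate 2 had 802 among 43139. The conservative list of the series, used for the results below unless another list is named, had 814 peaks among 54900 candidates. Its peaks had a median width of 276 bp, and their signal had a median of 101.7 and a highest value of 619.3. The signal is the authors' own value per peak, its scale is not given in the sources used here, and it ranks peaks only within a list.

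The tagged gene itself had a listed peak upstream of its start. The gene ztf-29 (WBGene00013438) spans positions 11561152 to 11562663 of chromosome III in ce11, on the forward strand. The conservative and the full list each held 1 peak within 1000 bp of it, from 11560555 to 11560830. Its summit at 11560693 lay 459 bp upstream of the annotated gene start. Its signal of 69.1 put it at rank 754 of the 814 conservative peaks. Neither replicate listed this peak on its own. The candidate there had a signal of 29.9 and an irreproducible discovery rate (IDR) of 0.104 in replicate 1, and of 43.2 and 0.0371 in replicate 2, where 0.01 was the limit for a listed peak. No listed peak lay in the gene body.

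**Figure D1:**
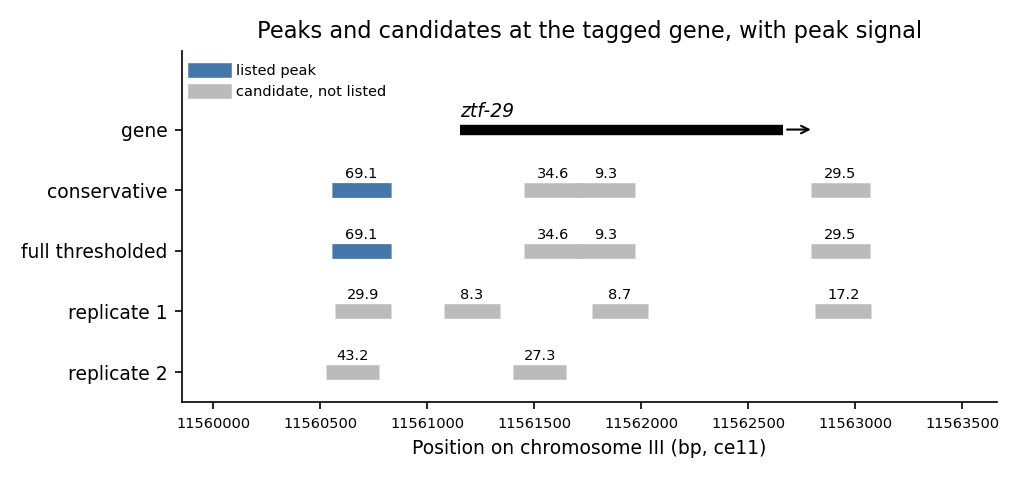
Position on chromosome III (bp, ce11) of the peaks (blue) and unlisted candidates (grey) around ztf-29 (black, arrow in the direction of transcription) in the 4 lists, with the peak signal above each bar. The blue peak with a signal of 69.1 lies upstream of the gene in both lists of the series, and in each replicate the same place holds a candidate only.

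The strongest listed peaks were at genes of small non-coding RNAs. Of 126 unlisted candidates within the IDR limit, described further below, 16 were stronger than every listed peak. Among those 126, 0 were near a tRNA, small nucleolar or small nuclear RNA gene. Of the 100 conservative peaks with the highest signal, 38 had their summit within 200 bp of a tRNA gene and 23 within 200 bp of a small nucleolar RNA (snoRNA) gene. In the whole list, 204 of the 612 annotated tRNA genes (33.3%, 95% exact interval 29.6 to 37.2) and 52 of the 346 snoRNA genes (15.03%, 11.4 to 19.2) had a summit within 200 bp. In replicate 1 alone the share of tRNA genes was 20.4%, and in replicate 2 alone 27.5%. The peaks near genes of tRNA, snoRNA or small nuclear RNA (snRNA) made up 250 of 814 (30.7%). When the peaks were shifted along their chromosomes 1000 times, a mean of 2.53 tRNA genes and 1.499 snoRNA genes had a summit, and the highest counts were 12 and 9. Of the 129 genes that the annotation calls snRNA, 11 had a summit (8.53%), against a mean of 0.475 in the shifts. Among them, named after their values were seen, were the SL2 spliced leader genes sls-2.1, sls-2.2, sls-2.4 and sls-2.9, and mir-1831, which lies inside sup-39 and shares its summit. The summit counted for sls-2.9 lies upstream of it, inside the lysine tRNA gene M01E5.t1. For these 3 classes the two-sided permutation p was 0.0020, the smallest that 1000 shifts can give (adjusted p = 0.00266 over 8 classes).

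The class that the annotation calls ncRNA had 315 of 7764 genes at a summit (4.06%), against a shift mean of 35.1 and a highest count of 63 (adjusted permutation p = 0.00266), and 2.47% in replicate 1 alone. The 255 peaks near this class were 31.3% of the list, and 144 of them were also near a tRNA, snoRNA or snRNA gene while 111 were not. Genes of microRNAs, which guide silencing of messages, had a summit in 6 of 261 cases (2.30%) against a shift mean of 1.10 (adjusted permutation p = 0.0160). That call did not pass among the 407 peaks with the stronger signal, nor with the summit required inside the gene body, and the share was 0.766% in each. Only 7 of 15363 piRNA genes (0.0456%) had a summit, against a shift mean of 44.2, and 8 of 2128 pseudogenes, against a mean of 27.7 (both adjusted permutation p = 0.00266). The piRNA call did not pass against failed candidates (0.614% of peaks against 1.08%, Fisher's exact test, adjusted p = 0.341) or inside the gene body, and the pseudogene call did not pass in replicate 1 alone (0.423%, adjusted permutation p = 0.0982). None of the 20 annotated rRNA genes had a listed summit, which allows a share of up to 16.8%. The replicates each showed the tRNA and snoRNA peaks. The share of peaks at tRNA genes was 24.9% in replicate 1 and 19.7% in replicate 2 (22.3% ± 3.67, SD, n = 2), and the share at snoRNA genes was 9.87% and 5.86% (7.87% ± 2.84, SD, n = 2).

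**Figure D2:**
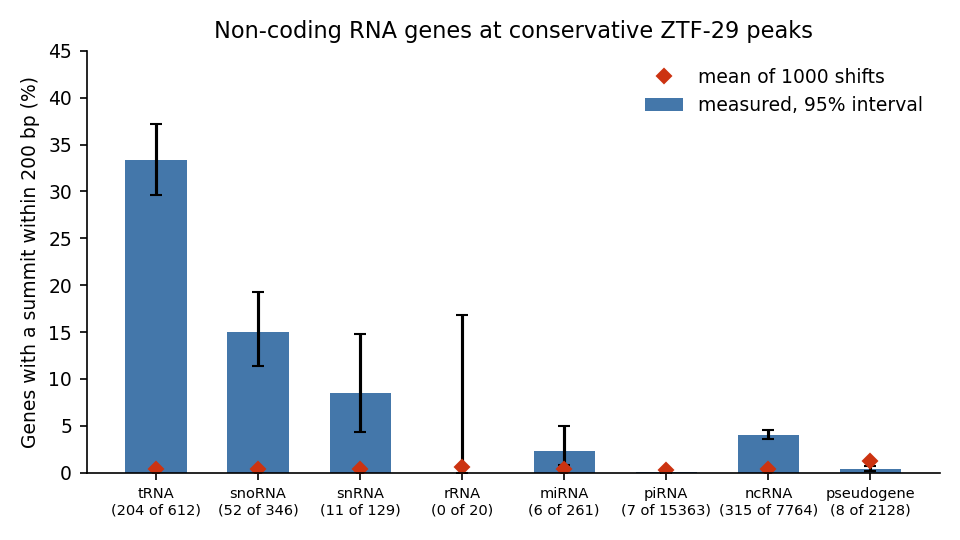
Share of annotated genes of each non-coding RNA class (%) with a conservative summit within 200 bp. Bars are measured shares with exact 95% intervals, diamonds are means of 1000 circular shifts, and tRNA genes (33.3%) and snoRNA genes (15.03%) stand above the other classes.

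The summits lay at different places at tRNA and snoRNA genes. At tRNA genes the median summit lay 20 bp downstream of the gene's 5' end, inside the gene (206 pairs of summit and gene, quartiles 7.25 and 35.8 bp). At snoRNA genes it lay upstream of the gene, with a median of -46 bp from the 5' end (53 pairs, quartiles -57 and -28 bp), and 47 of the 53 summits were upstream. At the 11 pairs of snRNA genes the median was 10 bp (quartiles -5.5 and 65.5 bp). The medians in the replicates were 16 and 19 bp at tRNA genes, and -42 and -51.5 bp at snoRNA genes. With the summit required inside the gene body, 25.33% of tRNA genes but 0.867% of snoRNA genes had a peak. No tRNA isotype passed Fisher's exact test against the rest. The shares among isotypes with more than 1 gene ran from 19.4% (6 of 31 tRNA-Val genes) to 45.7% (21 of 46 tRNA-Lys genes), and the smallest adjusted p was 0.957.

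**Figure D3:**
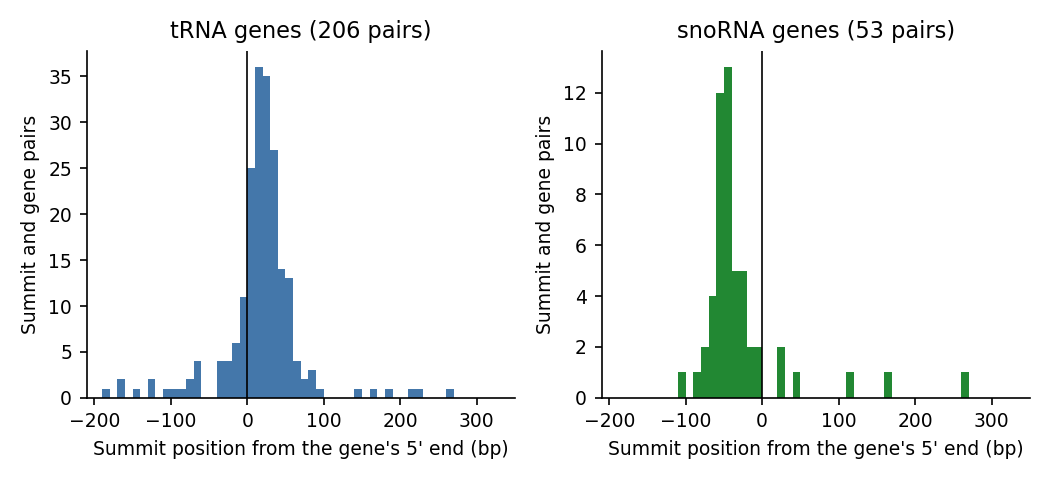
Distance in bp from the 5' end of the RNA gene to the conservative summits within 200 bp of it, for 206 pairs at tRNA genes (left) and 53 pairs at snoRNA genes (right). Negative values are upstream, and the bars count pairs in bins of 10 bp. The medians are 20 bp and -46 bp.

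Among the 25 strongest conservative peaks that both replicates listed, 11 were at tRNA genes, 8 at snoRNA genes and 6 at neither. The strongest, on chromosome V from 12303517 to 12303782 with a signal of 619.3, lay in an intron, within 200 bp of the snoRNA genes C51F7.3 and C51F7.4. The next were at the snoRNA genes W03C9.9 on chromosome II (signal 528.9) and T06C12.16 on chromosome V (492.5). The strongest tRNA peaks were at the isoleucine tRNA genes T21B4.t1 on chromosome II (449.1) and C42D8.t1 on the X chromosome (438.1). The list also held sup-5 (313.2), a tryptophan tRNA gene known for its amber suppressor alleles. A protein-coding start lay within 1000 bp of 8 of the 25 summits. It belonged to sre-23 (-619 bp), of a chemoreceptor family, and to the collagen gene col-85 (338 bp). The others were K12H4.5 (-525 bp), C04A11.5 (980 bp), Y43F8C.7 (793 bp), the kinase gene mpk-2 (639 bp), atx-2 (-62 bp) and rpl-3 (-279 bp). Of these 8 summits, those of sre-23, Y43F8C.7 and mpk-2 were also at a snoRNA gene and those of col-85 and C04A11.5 at a tRNA gene. The peak at atx-2, the worm gene for ataxin-2, an RNA-binding protein, had a signal of 305.4 and lay on chromosome III from 10461244 to 10461420. The peak at rpl-3, a protein of the large ribosomal subunit, had a signal of 293.7 and lay on chromosome III from 3867492 to 3867659.

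Promoters of protein-coding genes held a share of the peaks that was above that of candidates that failed. Of the 814 summits, 273 (33.5%, 30.3 to 36.9) lay from 500 bp upstream to 100 bp downstream of a protein-coding start, against 15.9% of the 53944 failed candidates (odds ratio 2.68, Fisher's exact test, two-sided, p = 1.18e-34). The share was 37.3% in replicate 1 and 25.19% in replicate 2 (31.3% ± 8.59, SD, n = 2), and it passed the test in each. Coding exons held 12 summits (1.47%, against 24.3% of failed candidates, Fisher's exact adjusted p = 5.01e-77), and 3' UTRs held 6 (0.737% against 2.45%, adjusted p = 0.000873). Introns held 239 (29.4%) and intergenic sequence 181 (22.2%), neither past the exact test (both adjusted p = 0.705), and 5' UTRs held 5 (0.614% against 0.866%, adjusted p = 0.705). Non-coding RNA genes held 98 (12.04% against 3.54%, exact adjusted p = 2.00e-24). With the peaks at tRNA, snoRNA and snRNA genes left out, a choice made after the data were seen, the promoter share was 42.02% of 564 peaks.

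Genes with a peak in this window were frequent among histones, ribosomal proteins and enzymes of oxidative phosphorylation. The background was 7309 genes with a candidate in the window, of which 329 (4.50%) had a peak. Of the histone genes in it, 9 of 31 had a peak (29.0%, odds ratio 8.90, adjusted p = 0.000177 over 31 lists, Fisher's exact test), with 11 of 25 in replicate 1 alone (odds ratio 22.3) and 8 of 29 in replicate 2 alone (9.39). Of the genes for cytoplasmic ribosomal proteins, 11 of 61 did (18.03%, odds ratio 4.79, exact adjusted p = 0.00112). Of those of oxidative phosphorylation, the mitochondrial production of ATP, 6 of 26 did (23.1%, odds ratio 6.46, exact adjusted p = 0.00879). Among the 407 peaks with the stronger signal only ribosomal proteins passed, with histones at 12.9% (exact adjusted p = 0.0651) and oxidative phosphorylation at 7.69% (0.945). The 9 histone genes shared 5 distinct peaks, since several lie in divergent pairs. The tests count both genes of a pair as independent. The p-values of histones, also in single replicates, are therefore too small, and the odds ratios are less certain than the gene counts imply. A summit at chromosome I, 9988973 (signal 160.5), served his-67 (-210 bp) and his-68 (-159 bp), and a summit at chromosome V, 16040590 (129.0), served his-3 (-218 bp) and his-4 (-75 bp). The strongest peaks of ribosomal protein genes were those of rpl-3, rpl-15 (225.5, -371 bp) and rps-24 (162.6, -307 bp). Replicate 1 listed 10 of the 11, and replicate 2 listed 10. The peak of rps-26, named after its values were seen, was also at the snoRNA gene F39B2.14. The summits of all 11 lay more than 200 bp upstream, between -245 bp at rps-20 and -452 bp at rpl-35, so that a window of 200 bp held 0 of them. The strongest peaks of the oxidative phosphorylation list were those of atp-2 (119.1, -270 bp) and atp-1 (110.9, 17 bp), subunits of the ATP synthase, and of cyc-1 (95.8, -312 bp), cytochrome c1. This list rested on replicate 1, with 26.1% of members at a peak (exact adjusted p = 0.0012), whereas in replicate 2 the share was 4.0% (adjusted p = 1.00).

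Other fixed lists with members at a peak did not pass Fisher's exact test (adjusted p from 0.767 to 1.00). With all protein-coding genes as background, chemoreceptors passed as less often at a peak (4 of 1308, 0.306% against 1.74%, exact adjusted p = 5.9e-05), but not against circular shifts, whose mean was 0.366% (adjusted permutation p = 1.00). Each of the following counts is out of the members in the background. Cell cycle genes had 2 of 12, cdc-25.2 (signal 80.5) and cdk-4 (72.9), and aminoacyl tRNA synthetases, which charge tRNAs, had 2 of 15, ears-2 (282.6, -19 bp) and kars-1 (83.0). Chromatin regulators had 2 of 19, lin-9 (81.6) and lin-52 (81.1), both of the DRM complex, and splicing factors had 2 of 28, snr-4 (223.6), at a peak that was also near the snRNA gene C52E4.8, and snr-1 (116.6). Nuclear hormone receptors had 4 of 93, with nhr-41 (134.5), nhr-256 (131.0) and nhr-49 (89.7), a regulator of fat metabolism, as the strongest. Chemoreceptors had 4 of 176, with srh-269 (118.2), sri-5 (113.1) and srd-44 (82.4). F-box genes had 3 of 88, fbxc-44 (140.0), fbxb-85 (92.2) and fbxa-83 (65.8). Lists with a single member at a peak were pharynx regulators (pha-4, 81.8), Argonautes (alg-1, 103.9), C2H2 ztf genes (ztf-29), translation factors (eif-3.C, 148.1), heat shock proteins (hsp-1, 84.1) and cuticle collagens (col-42, 90.3). The same held for neuropeptides (flp-23, 125.9), C-type lectins (clec-126, 166.0) and detoxification enzymes (gst-27, 172.5). The peaks of nhr-41, srh-269, srd-44, flp-23 and clec-126 were also at tRNA genes, and that of gst-27 at the snoRNA gene Y53F4B.48. Those of nhr-256 and col-42 held at least 2 consecutive copies of the telomeric repeat unit. Without such peaks nuclear hormone receptors had 2 of 93 and cuticle collagens 0 of 54. No member with a peak was found among epidermal and neuronal fate regulators, muscle structural genes, the Wnt pathway, apoptosis, sex determination and dosage compensation, or germline and P granule genes. The same was true of ceh homeobox and hlh genes, mitochondrial ribosomal proteins (0 of 31), the proteasome (0 of 20) and major sperm proteins. These 12 lists had few members in the background and none passed Fisher's exact test (smallest unadjusted p = 0.401), so the absence does not show avoidance. With a promoter window of 1000 bp upstream, 1 of 24 muscle structural genes and 1 of 15 neuronal fate regulators had a peak. The lists of body wall muscle, endoderm and intestine regulators, Hox, T-box and Notch pathway genes and vitellogenins had fewer than 5 members in the background and were not tested. None of their members had a peak.

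Of the 814 conservative peaks, 325 (39.9%) were listed in both replicates on their own and 200 in neither. Of the peaks of replicate 1, 321 of 466 (68.9%, 64.5 to 73.1) overlapped a listed peak of replicate 2 by at least 1 bp, and 318 of 802 in the other direction (39.7%, 36.2 to 43.1). In 1000 shifts the mean was 1.95 and the highest count was 7 (permutation p = 0.0020, the smallest that 1000 shifts can give). Of the peaks of replicate 1, 91.3% at snoRNA genes, 90.5% at tRNA genes and 59.2% in promoter windows were listed in replicate 2. Of those of replicate 2, 87.2%, 66.5% and 51.98% were listed in replicate 1. Among 803 conservative peaks with a candidate in both replicates, the signals of the replicates had a Spearman correlation of 0.51 and a Pearson correlation of 0.78. These are correlations across peaks, which are not independent replicates, and the Spearman value fell to 0.37 over the full list and 0.29 over 18955 candidates.

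Of the 4 kinds of peaks compared, the listed peaks of the replicates differed most in the share with telomeric repeat sequence. This is a contrast of membership in lists with an IDR limit, not of signal. Peaks with at least 2 consecutive copies of TTAGGC, the repeat unit of worm chromosome ends, within 50 bp of the summit were counted. They numbered 170 of 802 in replicate 2 (21.2%, 18.4 to 24.2) but 6 of 466 in replicate 1 (1.29%, 0.474 to 2.78). The mean over both was 11.2% ± 14.1 (SD, n = 2), and the shares differed by Fisher's exact test (adjusted p = 1.18e-28 over 4 kinds of peaks, a test chosen after the data were seen). In the failed candidates the repeat share was 1.13% in replicate 2 and 0.868% in replicate 1. Of all listed peaks, the shares in promoter windows (exact adjusted p = 1.52e-05), at snoRNA genes (0.0133) and at tRNA genes (0.0337) were higher in replicate 1. With the repeat peaks taken out of both totals, only the promoter share passed the test (37.6% and 29.3%, exact adjusted p = 0.0122), while 116 of 460 and 158 of 632 peaks were at tRNA genes (0.944) and 46 in each at snoRNA genes (0.184). These tests set a single library against another, over peaks. Of the 170 peaks, 127 (74.7%) overlapped a candidate of replicate 1 and 5 a listed peak of it. Of the 632 other replicate 2 peaks, 590 (93.4%) overlapped a candidate of replicate 1. The conservative list held 59 such peaks (7.25%, against 0.897% of failed candidates, Fisher's exact p = 1.40e-32). Of these, 47 were listed in replicate 2 and 5 in replicate 1, while 56 overlapped a candidate of replicate 1 and all 59 one of replicate 2. In replicate 1 alone the repeat share did not pass against failed candidates (1.29% against 0.868%, Fisher's exact p = 0.309). Nor did it with 3 consecutive copies (0.858% against 0.367%, exact p = 0.0975). It passed with 1 copy (6.22% against 4.12%, exact p = 0.0340) and with 4 (0.644% against 0.123%, exact p = 0.0225). All 59 lay in the outer parts of autosomes, when each was divided into 3 equal parts, and none on the X chromosome, 30 were in introns and 11 between genes, and none was near a tRNA, snoRNA or snRNA gene. The strongest, chosen after the data were seen, had its summit at position 19528724 of chromosome V, in an intron, with the start of Y43F8B.2 nearest (signal 169.7).

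**Figure D4:**
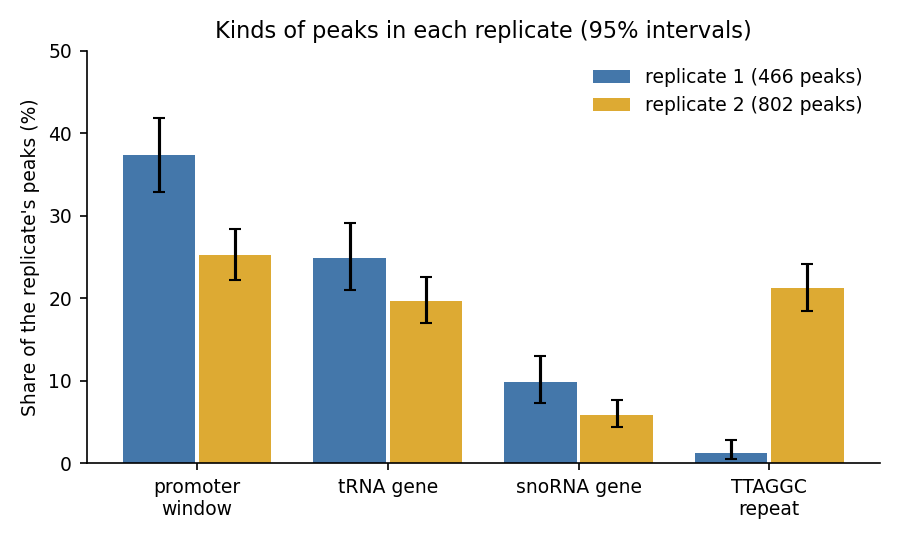
Share of each replicate's listed peaks (%) with the summit in a promoter window or within 200 bp of a tRNA or snoRNA gene. The last pair shows those within 50 bp of at least 2 consecutive copies of TTAGGC. Bars are single lists of 466 (replicate 1) and 802 (replicate 2) peaks with exact 95% intervals, and the repeat share is 1.29% in replicate 1 and 21.2% in replicate 2.

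The summits held fewer words made of A and T runs than their flanks. The 5 words with the smallest p among 2080 6-base words were all less frequent within 50 bp of the summit than in a flank of the same peak. They were AAAATT (11.8% against 41.9%), AAAAAT (14.1% against 45.6%), TAAAAA (6.76% against 31.7%), AAATTA (4.42% against 25.06%) and TGAAAA (8.60% against 30.7%), with adjusted p from 5.23e-42 to 2.42e-27 by the exact McNemar test. In all, 480 words were more frequent at summits and 395 less frequent. The words named next were chosen after their values were seen. The word GGCTTA, part of the telomeric repeat, was at 15.6% of summits against 2.83% of flanks (exact adjusted p = 1.10e-20), in the list of replicate 2 at 32.0% against 4.74%, and in that of replicate 1 at 5.58% against 2.15% (adjusted p = 0.0334). The words CGAACC (15.2% against 2.58%, exact adjusted p = 6.48e-18) and GTTCGA (17.4% against 5.28%, adjusted p = 4.22e-14) are part of the B box, an internal promoter element of tRNA genes. In the 475 peaks left after removing those at tRNA, snoRNA or snRNA genes and those with a copy of TTAGGC, GTTCGA was at 3.37% of summits against 4.0% of flanks (exact adjusted p = 0.894), CGAACC at 2.53% against 2.11% (0.961) and GGCTTA at 5.05% against 2.95% (0.283). There the word with the smallest p among those more frequent at summits was CCGCAC, at 13.5% of summits against 0.842% of flanks (exact adjusted p = 5.41e-13). It was followed by GCCGCA (13.7% against 1.47%) and GCGCGC (12.4% against 0.842%). These words are rich in G and C, and summits and flanks were not matched for base composition. The median GC at all 814 conservative summits was 50.5%. Whether the words reflect more than base composition was not tested.

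The X chromosome held more of the peaks than of the failed candidates. It had 172 of 814 summits (21.1%, 18.4 to 24.1) against 16.9% (Fisher's exact test, p = 0.00188), or 9.71 peaks per Mb, compared with 5.11 on chromosome V and 10.3 on chromosome III. Of the tRNA genes, 276 of 612 (45.1%) are on the X chromosome. With peaks at tRNA, snoRNA and snRNA genes left out, the share on the X was 14.7%, below that of failed candidates and not past the exact test (p = 0.175). In replicate 2 alone the X share was 19.3% and did not pass the exact test (p = 0.0788). On the autosomes, 64.3% of summits lay in the outer parts, against 73.2% of failed candidates (Fisher's exact p = 9.42e-07). In replicate 2 alone it was 71.4% (exact p = 0.476), and against chromosome length, where 66.7% lies in the outer parts, the share did not pass either (p = 0.209). The 59 conservative peaks with the telomeric repeat all lay in the outer parts. With them left out, a choice made after the data were seen, the share was 60.7% of 583 summits, against 73.2% of failed candidates (Fisher's exact p = 6.75e-11).

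The conservative and the full list of the series held largely overlapping peaks. Of the 814 conservative peaks, 734 (90.2%, 87.9 to 92.1) overlapped a peak of the full list, which had 1114. Of the full list's peaks, 380 had no overlap with the conservative list, and their median signal of 72.3 was below that of the 734 others, 107.7. Peaks with at least 2 consecutive copies of TTAGGC made up 24.5% of those 380 (93 peaks) and 7.49% of the others (55 peaks). The difference was past Fisher's exact test (p = 1.78e-14, a test chosen after the data were seen).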

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

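The pattern in this part was examined only after it was seen. Peaks passing the IDR limit between the replicates but absent from the conservative list numbered 126 of 940, a signal outside the lists used for every comparison above. Their median signal was 163.3, against 101.7 for the listed peaks of the same ranking, and 16 of them exceeded the strongest listed peak (619.3). The strongest, at position 15811110 of the X chromosome, had a signal of 3069.7, and the next, at position 11785823 of the X, 1950.1. Of the 126, 121 (96.0%) were intergenic, 0 were within 200 bp of a tRNA, snoRNA or snRNA gene, and 90 had another of them within 2000 bp. The reason for their absence is not given in the sources used here, and no explanation, technical or biological, was tested.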

How the results depend on the processing

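Chosen after the data were seen were the settings that left out or merged peaks, the other flank, the matched number of replicate 2 peaks and the failed candidates as background for RNA genes. Of 492 values under alternatives, 440 kept their direction and side of the threshold or their size, among them 86 of the 102 that answer a comparison. The promoter share (15.4% to 44.5%), the share of tRNA genes at a summit (20.4%, in replicate 1 alone, to 35.8%) and that of snoRNA genes (0.867% to 16.2%) passed the test under every alternative run except, for the RNA genes, the lists from which their own peaks were taken out, where tRNA, snoRNA and snRNA genes are at 0.000% by construction and 4 RNA classes passed. No paired analysis was possible because there is only 1 group. The limits of 2 libraries of unknown depth apply throughout.

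Without replicate 1 or 2 in turn, the X share was 19.3% to 22.5%, the share in autosome arms 62.6% to 71.4%, and the peaks at ztf-29 numbered 0 in each; that is, they are in the lists made from both replicates only. Summits in introns were 25.5% to 34.3% and oxidative phosphorylation genes at a peak 4.0% to 26.1%, with replicate 2 alone on the other side of the background in both. Without peaks at tRNA, snoRNA and snRNA genes, the X share was 14.7%, intergenic summits were 26.6%, and 266 words were more frequent at summits, or 254 when those with the telomeric unit were also left out. The word GTTCGA was then at 3.01% of summits, and at 3.37% with both left out, below the flanks. So were, with both left out, the telomeric words CCTAAG (1.26%), GCCTAA (0.000%), AGCCTA (1.89%) and CTAAGC (1.68%). The peaks left out there are those with TTAGGC, which fixes GCCTAA at 0 and lowers the words that overlap it, while the flanks were not filtered. A promoter window of 200 bp gave 33.0% intergenic summits, 0.000% of ribosomal protein genes and 1 list past the threshold in place of 3, as did the better-ranked part of the peaks, also 1. Chromosome length as background left 64.3% in the arms short of the threshold. Words of 8 bases gave 258. The rank correlation of signals was 0.37 over the full list and 0.29 over all candidates. The ribosomal protein summits lie over 200 bp upstream, which accounts for that window's value by construction, and fewer peaks enter the sets that leave some out. For the others the cause was not tested.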

Other observations

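Tests chosen only after the result was seen were those of strongly transcribed genes, of snoRNA gene copies and of words of 36 bases, and the tests of reads shared between repeat copies and between histone genes replaced earlier ones that could not decide. Apart from the RNA genes, some of the strongest conservative peaks were far from any annotated protein-coding start. The peaks on chromosome III with summits at 2497981 (signal 308.7) and 2499474 (286.1) lay between genes, 9991 and 8498 bp from the nearest start, and a peak with its summit at 4010345 of the same chromosome (361.1) was also intergenic. All 3 were listed in both replicates. A second peak near the tagged gene, outside the 1000 bp examined in the report, had its summit at 11558411, 2741 bp upstream of ztf-29, with a signal of 217.5 and rank 73.

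A hypothesis was that some peaks away from annotated tRNA, snoRNA, snRNA, rRNA and microRNA genes may lie on unannotated copies of the tRNA B box. A B box word was within 50 bp of 7 of 558 such summits (1.25%), against 0.775% of failed candidates (Fisher's exact test, p = 0.216), and in 5 of their flanks (exact McNemar test, p = 0.774). The difference did not pass, so these data neither excluded nor showed such sites. The same word was at 40.2% of summits at tRNA genes and at 19.2% of those at snoRNA genes.

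Peaks at tRNA and snoRNA genes could come from reads shared between identical gene copies. Every annotated snoRNA gene is unique in sequence. The share of unique genes with a peak, 15.03% (lower limit 11.4%, above the 2.60% that is the highest of the shifts), thus repeats the result above and decides nothing. Of the 50-base words within 100 bp of each of the 52 snoRNA summits, 100% occurred once in the genome. For 36-base words the lowest share at a summit was 92.8%. No bound was set beforehand for these summits, but the values argue against shared reads at snoRNA genes for reads of 50 bases or more. Of the tRNA genes of unique sequence, 19.6% (28 of 143, 13.4 to 27.04) had a peak. The share was 37.5% of those with identical copies (Fisher's exact test, p = 4.77e-05), so copies may add to the number of tRNA peaks. This comparison covers identical copies only, and a summit within 200 bp can lie in a neighbouring tRNA gene. Around the 189 tRNA summits, a median of 77.0% of 50-base words and 70.5% of 36-base words occurred once in the genome. Shared reads at tRNA genes therefore stay open. That any strongly transcribed gene collects signal stays open. Of all 82 annotated ribosomal protein genes, 13.4% (6.89 to 22.7) had a peak in the promoter window. This was below the share of tRNA genes, which was measured within 200 bp of the gene and so over another window. Among genes with a candidate in the promoter window, 18.03% of ribosomal protein genes had a peak, against 4.50% of all such genes. An immunoprecipitation of another factor was not analysed here. The design has a single group, and no biological explanation was tested.

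Among the 466 strongest peaks of replicate 2, 16.7% (13.5 to 20.4) had the repeat, against 1.29% of the 466 of replicate 1, which argues against weak peaks as the cause. Of 233 arrays with at least 4 exact copies of another 6-base unit, 6.01% (3.32 to 9.88) had a replicate 2 peak, against 30.6% of 422 arrays of TTAGGC (Fisher's exact test, p = 6.43e-15), a lower share that nevertheless did not reach the bound set for excluding repeats of any kind. The units were unlike each other, with 6 of 12 arrays of AAGCCC and 0 of 36 of AGGCAT at a replicate 2 peak. Both differ by 1 base from a rotation of TTAGGC or its reverse complement, as do AGCCTG (3 of 27), AAAGCC (2 of 6) and AAGTCT (1 of 12). The remaining peaks were at AAATTT (1 of 5) and AAATTG (1 of 4). Replicate 1 had a peak at 13 of the 422 arrays of TTAGGC and at 0 of the 233. Of the 50-base words within 100 bp of these summits, a median of 100% and a lower quartile of 99.3% occurred once in the genome, over the bound of 90% set beforehand for that length, while for 36-base words the median was 95.8% and the lower quartile, 86.1%, was under that bound. For reads of 50 bases or more this argues against reads shared between copies as the cause of the whole pattern, the read length is not given, repeats of other units stay open, and no biological explanation was tested.

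The peaks at histone, ribosomal protein and oxidative phosphorylation promoters could follow GC content, since the strongest candidate of those genes had a median GC of 48.5% within 50 bp, against 40.6% for other genes. With GC in a logistic model, the odds ratio of the 3 lists went from 6.42 (4.10 to 10.1) to 3.71 (2.30 to 5.97), which argues against GC as the whole cause and leaves a part of the excess to it. The model counts histone genes that share a peak as separate genes, so its intervals are too narrow. Of the words around the 5 histone summits, the lower quartile of those that occur once was 93.4% for 50 bases, over the same bound, and 84.3% for 36 bases, under it, with a median of 100% for both. For reads of 50 bases or more this argues against reads shared between near-identical histone genes as the whole cause. No biological explanation was tested, and the pattern was found and tested on the same data.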
